A study of Mus musculus with 16 samples.

How the data were processed

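Total RNA of pooled embryonic adrenals was reverse transcribed with Megaplex primers and read on TaqMan OpenArray microRNA panels, per the labels. RNA came from an RNAqueous Micro kit, and mice were C57BL/6, per the labels' characteristics. The titles of both E15.5 samples numbered 1 carry an R whose meaning is not given, and both were kept. The day a plug was found counted as E0.5. The deposited table holds threshold cycles (Ct) without normalization for 16 samples, 4 per group, and for 2 no-template controls. Its 846 wells carry 747 assay names, 741 of them miRNAs, and 43.8% of the wells of the samples have no Ct. The Ct values run from 10.2 to 34.9. The instrument software, thresholds and any preamplification are not given in the sources used here. A second deposited table gives the authors' fold changes per age on a log2 scale, headed as KO over WT. For all 272 single-well assays with a Ct in 16 samples its values equal the mean KO Ct minus the mean WT Ct after subtraction of the U6 well of the same sub-array, within 0.001 cycles. So the deposited log2 values above 0 stand for less RNA in KO. How undetected wells entered that table is not given in the sources used here.

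Each sample has 16 sub-arrays with 1 well each of U6, snoRNA135, snoRNA202, U87 and Y1. These sub-arrays fall into 2 sets of 8, called set 1 and set 2, whose control wells differ in Ct. What the sets are is not given in the sources used here. Levels were the mean Ct of the 5 controls, averaged over wells and then over names, minus the Ct of the assay. A Ct above 28 or a missing Ct counted as not detected and was set to 28. An assay was tested if it was detected in at least 3 samples of at least 1 group, which left 341. For 9 names with 2 wells, the wells were averaged after undetected wells were set to the limit, which dampens changes where 1 well is undetected. A level of a group with 0 samples detected is a bound, and its change is given as at least that large. An assay's level is not to be set against another assay's level, since amplification differs between assays. The number of samples, 4 per group, limits the precision, and the median standard error of a log2 change was 0.46.

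Group means were fitted to all 16 samples with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested assays and a threshold of 0.05. The contrasts were KO against WT at each age, the difference of these 2, and E16.5 against E15.5 in each genotype. Summary values of samples were compared with exact permutation tests, two-sided, 4 against 4, over 70 splits, with a smallest p of 0.0286. Lists of miRNAs were tested with camera at a preset correlation of 0.01, repeated with an estimated correlation, and with fry, on the same limma design, for lists of 3 or more tested assays. There were 22 lists. They were the let-7 family, the miR-17-92 and paralogous clusters, the miR-15, miR-16, miR-322 and miR-503 family, the miR-23/27/24 clusters, the families miR-29, miR-30, miR-34, miR-181 and miR-200, the miR-130, miR-301, miR-148 and miR-152 families, Hox cluster miRNAs, the Dlk1-Dio3 cluster, miRNAs of the Igf2/H19 locus, cAMP and steroidogenic cell miRNAs, the Sfmbt2 intron cluster, the miR-290 cluster, a Dicer-independent miRNA (miR-451), and markers of neural and chromaffin, endothelial, erythroid, white blood, and mesenchyme and muscle cells. Of these, 5 had fewer than 3 tested assays and no list test, and the Igf2/H19 list had 0. Fry, which asks whether a list moves on balance, gave an adjusted p under 0.05 for 4 lists at E15.5 (let-7, miR-34, miR-290 and cAMP) and for 13 at E16.5, each lower in KO, for 4 in the comparison of ages in WT (miR-29, miR-30, miR-34 and cAMP), each higher at E16.5, and for 0 in the comparison of ages in KO and in the difference.

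Assays named in the text came from a rule set before the data were examined: up to 12 largest falls and 12 largest rises past the threshold per contrast, the 10 smallest p where fewer than 10 passed, up to 4 members per list with the smallest p over both genotype contrasts, miR-451 and the small RNA controls. Assays named at 1 age were also followed at the other. The text names a part of these, and alternatives and samples standing apart were examined for all of them. The controls, each set against the mean of the other controls, differed between genotypes by -0.31 to 0.24 (exact permutation p of 0.0857 or more). This measure cannot show a move common to all 5. Samples with the same number were checked for pairing by the correlation of their deviations from the group means. At E15.5 the 4 same-number correlations were 0.33, 0.23, 0.15 and 0.11, so numbers were taken to pair samples there. At E16.5 they were -0.17, -0.05, 0.10 and -0.10.

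The limma fit was tested on simulated data. With the means and residual spreads of the 341 assays, and 200 assays per size changed in KO at E16.5 over 10 runs, 89.0% of assays changed by -3, 75.0% of those changed by -2 and 23.0% of those changed by -1 were called. False calls made up 4.10% of calls, and 0 calls were made in the simulated comparison at E15.5, where nothing was changed. The simulated assays varied independently, without shifts of whole samples and without a detection limit. These rates therefore do not carry over to the real data, where samples shift as a whole and wells lie at the limit. Alternatives were the miRNA median, each control alone and no normalization, Ct limits of 26 and none, undetected values left out, stricter and looser filters, subsets of samples, a replicate block, other limma options and each sample left out in turn. After the data were seen, scaling to controls or miRNA median of the same set, to the U6 well of the same sub-array, a choice of 1 well of duplicates and each set alone were added. The panel was analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.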

Results

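MicroRNA levels were measured in adrenal glands of mouse embryos at embryonic days E15.5 and E16.5. In the knockout (KO) embryos a Cre recombinase under control of Sf1, the gene of a transcription factor of steroidogenic cells, acted on floxed Dicer, which encodes the RNase that cuts miRNA precursors to their mature length. Control (WT) embryos were littermates without Cre. Each of the 4 groups held 4 samples, 16 in all. Adrenals of KO and control littermates were pooled separately, with 4 litters given as the biological replicates. The comparisons ask which miRNAs of the fetal adrenal depend on Dicer in steroidogenic cells, and whether that differs between the 2 ages. The Dicer transcript was not analysed here, so the labels were not checked against the deleted gene.

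The assay was a real-time PCR panel with 741 miRNA names and 5 small RNA controls that are not made by Dicer: the RNAs U6, snoRNA135, snoRNA202, U87 and Y1. A threshold cycle (Ct) is the cycle at which a well's signal crosses a threshold, so 1 cycle less stands for about 2 times the template. Levels are given as the mean Ct of the controls minus the Ct of the miRNA, on a log2 scale, and a Ct above 28 or a missing Ct counted as undetected and was set to 28. Between 267 and 356 miRNA assays were detected per sample. The control mean Ct lay between 16.3 and 18.0. In all, 341 assays were tested.

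At E16.5 the median miRNA level of each KO sample, set against the small RNA controls, lay below that of each WT sample. The median level per sample was -4.98 ± 0.21 in WT (SD, n = 4) and -6.03 ± 0.42 in KO (SD, n = 4). The difference was -1.06, or 2.08-fold lower (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 unpaired samples allow). Over the 18 sample measures tested this way the adjusted value was 0.206, above the threshold of 0.05. KO and WT pools came from littermates, and if samples are paired, 4 pairs cannot give an exact sign-flip p under 0.05. At E15.5 the medians were -5.72 ± 0.19 in WT and -6.37 ± 0.76 in KO (SD, n = 4 each), a difference of -0.65 that was within the spread of the samples (exact permutation test, two-sided, p = 0.229). Here 2 KO samples, replicates 3 and 4, lay at -7.03 and -7.01, while replicates 1 and 2 lay at -5.89 and -5.57. With the median of the miRNAs themselves as reference the difference at E16.5 was -0.04 (exact permutation p = 0.657), as that scaling removes a shift common to most miRNAs, and with the miRNA median of each set of sub-arrays it was -0.22 (exact permutation p = 0.0571). Without normalization it was -0.46 (exact permutation p = 0.2). Without WT replicate 1, 2 or 4 the difference was -1.03, -0.99 or -1.05 (exact permutation p = 0.0571 each).

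**Figure D1:**
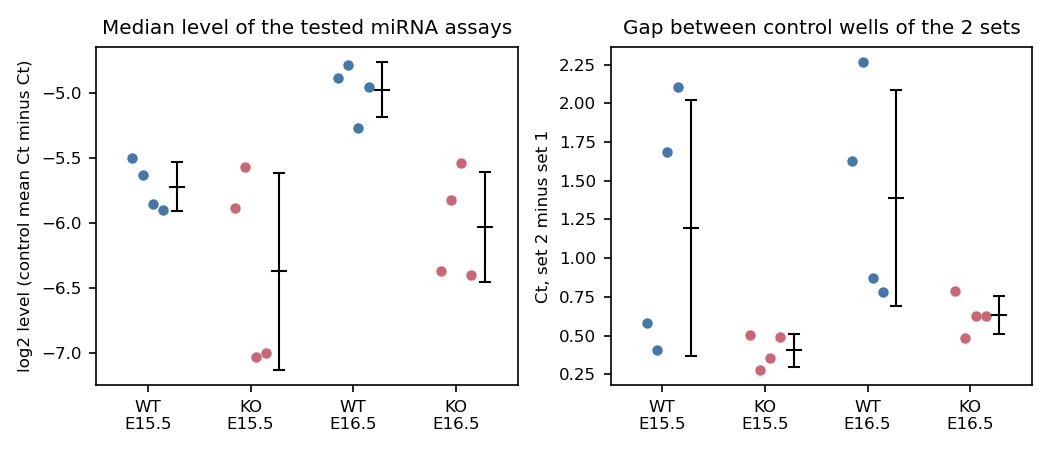
Left, the median log2 level of the tested miRNA assays in each sample (points) by genotype and age, and right, the Ct of control wells on set 2 of the sub-arrays minus that on set 1. Bars show the mean ± SD of 4 samples, and at E16.5 the KO medians, -6.40 to -5.54, lie below all WT medians, -5.27 to -4.79.

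The number of miRNA assays detected did not separate the genotypes. It was 333 ± 16.2 in WT and 308 ± 28.6 in KO at E15.5 (SD, n = 4 each, exact permutation test, two-sided, p = 0.171), with 267 in KO replicate 4. At E16.5 it was 340 ± 12.6 in WT and 326 ± 24.7 in KO (SD, n = 4 each, exact permutation p = 0.371). The control wells themselves differed between the 2 sets of sub-arrays of a sample, by 1.20 ± 0.83 cycles in WT and 0.41 ± 0.11 in KO at E15.5 (exact permutation p = 0.0857, n = 4 each). At E16.5 the gap was 1.39 ± 0.70 cycles in WT and 0.63 ± 0.12 in KO (exact permutation p = 0.0571, n = 4 each).

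At E15.5 some miRNAs passed the threshold as lower in KO adrenals. Of 341 assays, 43 fell and 0 rose (limma, adjusted p under 0.05, 110 at an unadjusted p under 0.05). Against the small RNA controls the log2 change was below 0 for 275 of the 341 (80.6%), so the called assays do not mark the extent of the fall. miR-98, a let-7 family member, was detected in all WT samples and in none of the KO samples, at least 106-fold lower (log2 change -6.72 with KO at the detection limit, SE 0.41, limma adjusted p = 3.45e-09). The miRNAs miR-34b-3p and miR-34c, made from a shared locus that the tumour suppressor p53 activates, were 7.76-fold and 7.72-fold lower (log2 changes -2.96, SE 0.35, and -2.95, SE 0.44, n = 4 each). miR-21, an abundant miRNA of many tissues, was 3.81-fold lower (log2 change -1.93, SE 0.43, limma adjusted p = 0.00871), and miR-10a, encoded in a Hox gene cluster, was 3.53-fold lower (-1.82, SE 0.34, limma adjusted p = 0.00213).

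Further falls at E15.5 were seen for miR-674 (log2 change -5.20, SE 1.36), which was detected in 1 of 4 KO samples, and miR-365 (-4.35, SE 0.57). miR-672 (-2.92, SE 0.35), miR-193# (-2.88, SE 0.52), miR-107 (-2.51, SE 0.50), miR-182 (-2.51, SE 0.56) and miR-34c# (-2.46, SE 0.58) were lower as well, where # marks the minor arm of a hairpin. miR-202, a miRNA of the gonads, changed by -2.71 (SE 0.45, limma adjusted p = 0.00061). Every one of the KO samples lay below every WT sample for miR-98, miR-34b-3p, miR-21 and miR-10a.

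By family, let-7, which promotes differentiation, had the largest share of calls at E15.5. Of its 10 tested assays 8 fell, and 9 when adjusted over the list alone. let-7d fell 4.14-fold (log2 change -2.05, SE 0.42) and let-7g 3.20-fold (-1.68, SE 0.41). Compared with the other assays the let-7 list was lower (camera adjusted p = 0.000117 on the limma design, adjusted p = 0.495 with an estimated correlation). The list includes miR-98, with KO at the detection limit, and was not tested without it. Its median log2 change was -1.46 against a mean of -1.91. In the miR-34 and miR-449 family 3 of 5 assays fell, and 3 adjusted over the list alone (camera adjusted p = 0.0156, limma design, adjusted p = 0.495 with an estimated correlation). The miR-290 cluster, which is typical of embryonic stem cells and germ cells, had 2 of 3 assays lower, 3 adjusted over the list alone. Its members miR-293 and miR-292-3p changed by -3.57 (SE 0.43) and -1.97 (SE 0.58) (camera adjusted p = 0.0209, limma design, adjusted p = 0.495 with an estimated correlation).

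Few assays of the larger families passed at this age. Of 17 assays of the miR-17-92 and paralogous clusters, which promote proliferation, 1 fell (0 adjusted over the list alone), miR-93 by a log2 change of -1.17 (SE 0.34). Of 10 assays of the miR-15, miR-16, miR-322 and miR-503 family 1 fell, miR-424 (-1.66, SE 0.48), and 2 adjusted over the list alone. In that family miR-322 changed by only -0.11 with the control wells of its own set of sub-arrays. Of 8 assays of the miR-130, miR-301, miR-148 and miR-152 families 1 fell, miR-148b (-1.71, SE 0.46), and 1 adjusted over the list alone. In the Dlk1-Dio3 imprinted cluster 6 of 57 assays fell, 2 adjusted over the list alone. Of 6 Hox cluster assays 1 fell and of 6 cAMP and steroidogenic cell assays 2 fell, 1 and 3 adjusted over the list alone. In the Sfmbt2 intron cluster 1 of 7 assays fell, miR-669a (-2.08 with KO at the detection limit, SE 0.64), and 1 adjusted over the list alone. The miR-29 family with 3 assays, the miR-30 family with 8 and the miR-23/27/24 clusters with 7 had 0 called, and 2, 5 and 0 adjusted over each list alone.

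Few markers of other cell types passed at E15.5, when 43 of all 341 assays did. Of 13 neural and chromaffin cell assays 1 fell, miR-182, and 1 adjusted over the list alone. Of 5 white blood cell, 13 mesenchyme and muscle and 4 miR-200 epithelial assays 0 were called by limma, and 0 adjusted over each list alone. The neural, white blood cell and miR-200 lists did not differ from the other assays (camera adjusted p = 0.805, 0.683 and 0.372, limma design), so these counts do not show that such markers were spared. The mesenchyme and muscle list had a mean log2 change of -0.01, higher than the other assays (camera adjusted p = 0.0156, limma design, adjusted p = 0.847 with an estimated correlation). The endothelial miR-126 had a log2 change of -0.69 (SE 0.48, limma adjusted p = 0.339). miR-451, a red cell miRNA that matures without Dicer, had -0.61 (SE 0.46, limma adjusted p = 0.381). The erythroid list, the endothelial list and the miR-181 family had 2 tested assays each, with 0 called at either age by limma, and the Igf2/H19 list had 0 tested assays. Samples with the same number deviated together at E15.5, and a limma fit with the number as a block called 19 assays, 18 of them among the 43. In that fit let-7g (adjusted p = 0.0628), miR-93 (0.137), miR-424 (0.0702), miR-148b (0.0604) and miR-669a (0.0599) no longer passed limma's threshold.

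The E15.5 count moved with individual samples. It was 14 without KO replicate 3, 17 without KO replicate 4, 20 without WT replicate 3, 23 without WT replicate 4 and 112 without KO replicate 2. It was 27 without both samples numbered 1, whose titles carry an R that is not explained. Without KO replicate 3, let-7g, miR-34c#, miR-93, miR-148b, miR-292-3p, miR-424, miR-669a and miR-674 no longer passed (limma adjusted p from 0.0634 to 0.13), and 7 named assays no longer did without KO replicate 4, 6 without WT replicate 3, 5 without WT replicate 4, 2 without KO replicate 1 or WT replicate 1 and 1 without WT replicate 2. With the control wells of each assay's own set of sub-arrays 30 assays passed, 25 of them among the 43, and miR-34c changed by -2.55. All assays had a median log2 change of -0.62 in the main fit. Scaled to the miRNA median 20 assays passed, 3 higher and 17 lower, with 17 among the 43. On that scale the means of let-7 (-1.12), miR-34 (-1.12), miR-290 (-1.52), miR-29, miR-30 and cAMP lists stayed below 0, while those of the other 11 lists lay above 0. The let-7 mean includes miR-98, set to the limit in all KO samples.

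At E16.5 more assays passed: 144 of 341 assays fell and 2 rose in KO (limma, adjusted p under 0.05, 184 at an unadjusted p under 0.05). miR-98 was again detected in every WT sample and in 0 KO samples, at least 253-fold lower (log2 change -7.98 with KO at the detection limit, SE 0.41, limma adjusted p = 2.21e-10). miR-202 was at least 29.6-fold lower (-4.89, SE 0.45), with 0 of 4 KO samples detected. miR-34c fell 17.2-fold (-4.10, SE 0.44), miR-34b-3p 12.1-fold (-3.59, SE 0.35) and miR-21 6.69-fold (-2.74, SE 0.43, limma adjusted p = 0.000249). miR-690 rose 4.04-fold (2.02, SE 0.46, limma adjusted p = 0.00526).

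The other large falls at E16.5 included miR-674 (-5.24, SE 1.36) and miR-194 (-4.62, SE 1.16), each detected in 1 of 4 KO samples, and miR-365 (-3.54, SE 0.57) and miR-34c# (-3.61, SE 0.58). Over the alternatives the change of miR-194 ran from -9.79 to -1.32, and it missed the limma threshold in 3 of 25. That of miR-674 ran from -6.51 to -1.41, and it missed the threshold in 2 of 30. miR-672 (-2.80, SE 0.35), miR-107 (-2.50, SE 0.50), miR-193# (-2.40, SE 0.52) and miR-182 (-1.91, SE 0.56) were lower at this age as well. The second rise was miR-2182, with a log2 change of 1.37 (SE 0.51, limma adjusted p = 0.0412). It did not pass with controls taken from its own set of sub-arrays (0.99, limma adjusted p = 0.0726), whereas miR-690 did (1.64, limma adjusted p = 0.00314).

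**Figure D2:**
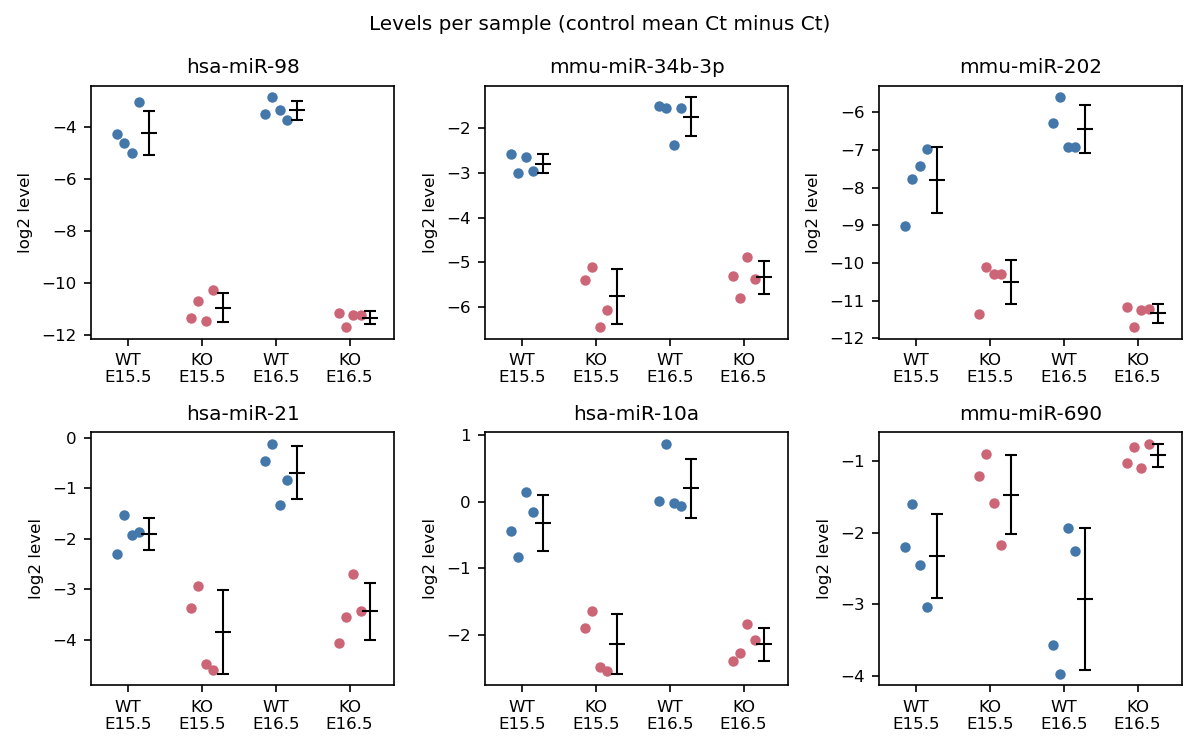
Log2 level (control mean Ct minus Ct) of 6 miRNAs in each sample, by genotype and age, with bars for the mean ± SD of 4 samples. miR-98 lies at the detection limit in all 8 KO samples, and miR-690 at E16.5 has a mean of -0.92 in KO and -2.93 in WT.

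Most members of several families fell at E16.5. In the let-7 family 9 of 10 assays fell, and 9 adjusted over the list alone, among them let-7d (-2.13, SE 0.42), let-7f (-1.82, SE 0.41) and let-7g (-1.75, SE 0.41). Against the other assays the list was lower (camera adjusted p = 0.00174, limma design, adjusted p = 0.693 with an estimated correlation). It includes miR-98, with KO at the detection limit, and was not tested without it. The median log2 change of the list was -1.57 against a mean of -2.19. All 5 assays of the miR-34 and miR-449 family fell, 5 adjusted over the list alone, with a median log2 change of -3.59 (camera adjusted p = 0.000857, limma design, adjusted p = 0.163 with an estimated correlation). All 3 assays of the miR-290 cluster fell, 3 adjusted over the list alone: miR-293 (-4.52, SE 0.43), miR-292-3p (-4.32, SE 0.58) and miR-295 (-3.18, SE 0.50), with miR-293 and miR-295 undetected in KO, so that these are lower bounds. For miR-292-3p the KO samples other than replicate 3 lay at -11.3 to -11.15, at or near the detection limit. Compared with other assays that list had a camera adjusted p of 0.00115 on the limma design, and an adjusted p of 0.151 with an estimated correlation.

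Assays of families tied to proliferation and differentiation fell as well. Of the 17 assays of the miR-17-92 and paralogous clusters 11 fell, 12 adjusted over the list alone, with miR-18a# at -1.84 (SE 0.41), miR-106b at -1.59 (SE 0.37) and miR-93 at -1.42 (SE 0.34). Of 10 assays of the miR-15, miR-16, miR-322 and miR-503 family 3 fell, 3 adjusted over the list alone, including miR-424 (-2.12, SE 0.48) and miR-16 (-1.25, SE 0.40). In that family miR-322 changed by only -0.21 with the control wells of its own set of sub-arrays. Of the miR-30 family 7 of 8 fell, 7 adjusted over the list alone, with miR-30e at -1.99 (SE 0.48) and miR-30b at -1.73 (SE 0.42). In the miR-23/27/24 clusters 5 of 7 fell, 6 adjusted over the list alone, with miR-27b at -1.52 (SE 0.42) and miR-24 at -1.22 (SE 0.39). Of the miR-130, miR-301, miR-148 and miR-152 families 6 of 8 fell, 7 adjusted over the list alone, with miR-148b at -1.68 (SE 0.46). In the miR-29 family 2 of 3 fell, 3 adjusted over the list alone, with miR-29b at -1.94 (SE 0.56). These 6 lists did not differ from the other assays by camera (adjusted p between 0.163 and 0.705, limma design).

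Genomic clusters held lower assays too. In the Dlk1-Dio3 cluster, imprinted and expressed from the maternal allele, 27 of 57 assays fell and 28 adjusted over the list alone, such as miR-337-3p (-1.92, SE 0.38), miR-494 (-1.73, SE 0.42) and miR-431 (-1.60, SE 0.38). Its mean log2 change of -1.12 lay near the median of all assays, -1.03 (camera adjusted p = 0.492, limma design). Of 6 Hox cluster assays 2 fell, 4 adjusted over the list alone: miR-10a (-2.34, SE 0.34) and miR-196A (-2.04, SE 0.45). Of 7 Sfmbt2 intron cluster assays 4 fell, 4 adjusted over the list alone, with miR-669a at -2.20 (SE 0.64) and miR-467c at -1.20 (SE 0.36). Of 6 cAMP and steroidogenic cell assays 4 fell, 4 adjusted over the list alone, with miR-202, miR-21 and miR-210 (-1.48, SE 0.37), the last a miRNA induced by low oxygen.

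Of 13 neural and chromaffin cell assays at E16.5 2 fell, 2 adjusted over the list alone, with miR-128a at -1.79 (SE 0.48) and miR-182. Of 5 white blood cell assays and 4 miR-200 epithelial assays 0 were called, 0 adjusted over each list alone. The neural and white blood cell lists did not differ from the other assays (camera adjusted p = 0.488 and 0.242, limma design). The miR-200 list was higher than the other assays by camera (adjusted p = 0.0229, limma design, adjusted p = 0.269 with an estimated correlation), over log2 changes from -0.60 to 1.89. The upper value is that of miR-141#, an assay that also gave a signal in a no-template control, and scaled to the miRNA median the list did not differ (camera adjusted p = 0.245, limma design). Of 13 mesenchyme and muscle assays 2 fell, 0 adjusted over the list alone: the muscle miRNAs miR-1 (-3.61, SE 1.20, limma adjusted p = 0.0251) and miR-133b (-2.56, SE 0.98, limma adjusted p = 0.0444). WT replicate 2 held levels of these muscle miRNAs of -1.95 and -0.51, against -8.08 to -6.47 and -6.62 to -5.33 in the other WT samples. Without that sample neither passed (limma adjusted p = 0.093 and 0.13), nor did they without KO replicate 1 (0.0773 and 0.113) or KO replicate 4 (0.0758 and 0.107), and miR-133b did not without WT replicate 1 (0.0609). miR-126 had a log2 change of 0.17 (SE 0.48, limma adjusted p = 0.773) and miR-451 of -0.82 (SE 0.46, limma adjusted p = 0.151).

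The size of the E16.5 list depended on scaling. With the control wells of each assay's own set of sub-arrays 107 assays passed. Of the 146, 93 were among them and 7 were not tested that way. There miR-34c changed by -3.73 and miR-34c# by -3.99, so the size of the falls above depends on which control wells are used. Scaled to the miRNA median 39 assays passed, 15 higher and 24 lower, and 26 of the 146 were among them. On that scale the list means of let-7 (-1.18), miR-34 (-2.05), miR-290 (-2.99) and miR-17-92 (-0.43) stayed below 0, while those of miR-15/16 (0.15), neural (0.18) and white blood cell (0.52) assays turned above it. The let-7 mean includes miR-98, set to the limit in all KO samples. The count was 97 without WT replicate 1, 83 without WT replicate 2, 92 without KO replicate 1 and 94 without KO replicate 4. Of the 58 named assays that passed, 17 no longer did without WT replicate 2 (limma adjusted p up to 0.153), miR-16, miR-24, miR-467c and miR-2182 among them, 14 without KO replicate 4, 13 without WT replicate 1, 12 without KO replicate 1, 3 without KO replicate 2 and 2 without each of KO replicate 3 and WT replicates 3 and 4. In the authors' deposited table, which gives KO minus WT Ct against U6 so that values above 0 stand for less RNA in KO, miR-21 stood at 2.24, miR-10a at 2.00, miR-34b-3p at 3.25 and miR-690 at -1.92 at E16.5. There miR-194 stood at 0.80, a much smaller fall than the one found here, and how undetected wells entered that table is not given.

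The assays that fell at E15.5 were largely among those that fell at E16.5. Of the 43 assays, 41 fell at both ages, against 18.2 expected of independent lists (Fisher's exact test, two-sided, p = 3.93e-15). Both comparisons used the same estimate of spread for each assay, fitted over all samples, and assays are not independent. Assays of low spread can thus pass at both ages together, so this p is not a valid measure of the overlap. miR-125a-5p and miR-369-5p, named here after their values were seen, passed at E15.5 alone. Across the 341 assays the changes at the 2 ages had a Pearson r of 0.730 and a Spearman rho of 0.671 (across assays, which are not independent replicates). The 2 ages shared no samples but shared the estimate of spread of each assay.

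**Figure D3:**
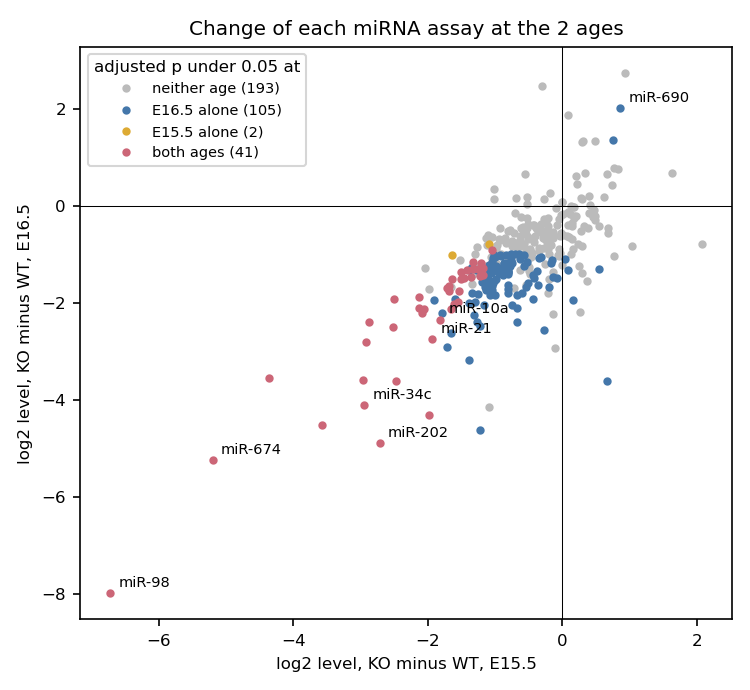
Each point is a miRNA assay, with its log2 change (KO minus WT) at E15.5 on the horizontal axis and at E16.5 on the vertical axis, coloured by where its limma adjusted p was under 0.05. Most points lie below 0 at both ages, and 41 assays passed at both.

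The genotype effect did not differ measurably between the ages for single miRNAs. The test of the difference called 0 assays (limma, lowest adjusted p = 0.986, with 13 at an unadjusted p under 0.05), although E16.5 had the larger list. Adjusted over the list alone, miR-292-3p, miR-295, miR-29b and miR-202 passed in this difference. The differences with the smallest p were those of miR-202 at -2.17 (SE 0.63) and miR-292-3p at -2.34 (SE 0.82), each further below WT at E16.5. In KO, miR-202 was detected in 2 of 4 samples at E15.5 and in 0 at E16.5, miR-295 in 0 at both ages and miR-29b in 3 and 2, so the detection limit sets part of these differences. It also bears on miR-292-3p, whose KO samples at E16.5 other than replicate 3 lay at -11.3 to -11.15, at or near that limit. By list, the miR-34 and miR-449 family was lower in this difference than other assays (camera adjusted p = 0.00939, limma design), but not with an estimated correlation (adjusted p = 0.435) or by fry, which tests a list by itself (adjusted p = 0.195, limma design), and 2 of its 5 assays, miR-34b-5p and miR-34c#, were detected in 2 or fewer KO samples at each age. The miR-290 cluster allows no such test, as in KO miR-295 was undetected at both ages and miR-293 at E16.5. In WT, miR-202 was higher at E16.5 than at E15.5 by 1.35 (SE 0.45), an unadjusted limma p of 0.0077.

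Between E15.5 and E16.5 no single miRNA passed the test in either genotype. In WT 0 assays were called (limma, lowest adjusted p = 0.17, with 65 at an unadjusted p under 0.05) and the median log2 change was 0.62. That median depended on scaling. It was 0.088 with the miRNA median, 0.30 with U6 alone and 0.87 with snoRNA135 alone, with 28, 15 and 125 assays at an unadjusted limma p under 0.05. miR-29a and miR-29b, which target collagen mRNAs, had log2 changes of 1.82 (SE 0.54) and 1.79 (SE 0.56), miR-223, a miRNA of myeloid cells, 1.28 (SE 0.42), miR-34b-3p 1.05 (SE 0.35) and miR-2146 1.40 (SE 0.36). As miR-29b was detected in 1 of 4 WT samples at E15.5, its change is measured from the detection limit, and it is 1 of the 3 assays of its list. By list the miR-29 and miR-30 families were higher at E16.5 in WT than other assays (camera adjusted p = 0.0395 for both, limma design, adjusted p = 0.673 and 0.798 with an estimated correlation). Tested by themselves with fry, the miR-29 (adjusted p = 0.0478), miR-30, miR-34 and cAMP lists (adjusted p = 0.0487 each) were higher at E16.5 in WT on the limma design. These list tests of age were run on the main scaling alone. Adjusted over the list alone, 5 miR-30, 4 cAMP, 3 miR-29, 2 white blood cell and 1 each of the miR-34, miR-130 and miR-290 list assays passed in WT, and 1 miR-29 and 1 miR-200 assay in KO. The miR-130 list assay, miR-148b-5p, and the miR-200 list assay, miR-141#, were undetected at E15.5 in those groups. In KO 0 assays were called (limma, lowest adjusted p = 0.252, with 22 at an unadjusted p under 0.05), with a median of 0.24. Here miR-29a had 1.89 (SE 0.54), miR-223 1.09 (SE 0.42) and miR-2146 1.41 (SE 0.36).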

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

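The tests of the let-7 family loss, of control wells, of RNA amount, of Dicer dependence and of set 2 fragments were chosen after the results were seen, as were the wording of the third pattern and its list of fragments, and the tests on well failure, KO runs and other splits were set out before.

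miR-98 was detected in all 8 WT samples, at a Ct of 19.8 to 22.8, and in none of the 8 KO samples. Random failure of wells is argued against, since 1.45% of the KO wells of assays with a similar WT Ct lacked a Ct within the limit (10 of 688 wells). A loss equal to that of the rest of let-7 is argued against as well, because miR-98 at the limit differed from the next let-7 assay by -5.85 on the log2 scale. The count of other assays with this pattern was 0, and a fault of this assay in the KO runs cannot be told apart from a true loss, since the runs are not labelled.

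The lower median level of miRNAs in KO at E16.5 could come from the reference. Control wells that differ between sets are argued against as the whole cause, since with each set on its own control wells the shift was -0.99. Each control alone gave a shift, and the nearest to 0 was -0.86. This cannot exclude a joint move of the controls, as all 5 were earlier in KO. Without normalization the median log2 change of the assays was -0.44, against -1.03 with it, so the controls make up part of the shift. Less RNA in KO reactions would give later controls, and the mean control Ct of KO minus WT was -0.59 (exact permutation p = 0.114), earlier in KO. All 5 controls were earlier, U6 by -0.46 (exact permutation p = 0.371), snoRNA135 by -0.77 (p = 0.0571), snoRNA202 by -0.56 (p = 0.0571), U87 by -0.40 (p = 0.286) and Y1 by -0.78 (p = 0.0286, adjusted over 18 measures 0.206). This goes against less RNA, but since the mean did not pass, that explanation stays open. Loss of Dicer products, the biological explanation, stays open too. miR-451 had a log2 change of -0.82 (SE 0.46), within 2 SE of both 0 and the median of -1.03. It could not decide this at any value, as it is a red cell miRNA and the Cre acted under control of Sf1, a gene of steroidogenic cells.

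A group of set 2 assays, led by miR-690 and miR-2182, was level or higher in KO at E16.5 while most assays were lower. The control wells of set 2 are argued against for miR-690, which stayed past the limma threshold at a log2 change of 1.64 with its own set's controls. Whether the assays read fragments of tRNA or rRNA, which need no Dicer, stays open. A list of 9 such names (miR-712, miR-720, miR-1274A, miR-1937B, miR-1937C, miR-2134, miR-2135, miR-2138 and miR-2146), lay 1.38 above the other 92 set 2 assays at E16.5, but it was chosen after such assays had been seen level or higher, so this cannot test the explanation. That list does not hold miR-690 or miR-2182, whose origin stays open.

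In 24 of 367 groups of 4 samples a sample stood apart from the others, and chance gives about 1 in 20, a rate that does not hold where wells were set to the detection limit. Groups with all samples undetected were left out, a step added after such groups had been seen among those standing apart. KO samples at E16.5 were replicate 2 for miR-674 at -6.11, miR-194 at -6.81 and miR-345-3p at -11.70, replicate 3 for miR-292-3p at -9.96, miR-223 at -1.16 and miR-15b at -1.83, and replicate 4 for miR-494 at -6.03 and miR-15a at -6.46. KO samples at E15.5 were replicate 1 for miR-202 at -11.36, replicate 2 for miR-193# at -6.98 and replicate 3 for miR-148b-5p at -11.46. WT samples at E16.5 were replicate 3 for miR-34b-3p at -2.38 and miR-193# at -4.61, replicate 2 for miR-10a at 0.87 and replicate 4 for miR-18a# at -6.42. WT samples at E15.5 were replicate 4 for miR-295 at -11.24, miR-126# at -11.24, miR-615 at -3.68 and miR-30b at 0.086, replicate 3 for miR-29b at -9.11 and miR-30a-5p at -1.18, and replicate 2 for miR-676 at -5.17. The values given for miR-345-3p, miR-202, miR-148b-5p, miR-295 and miR-126# are undetected wells set to the limit, not measured levels. For miR-674, miR-194 and miR-29b the other samples of the group were undetected. The control mean Ct was highest in WT replicate 3 at E15.5, 17.8, and lowest in KO replicate 2 at E16.5, 16.3, each apart from its group.

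The difference of the genotype effect between the ages was lower than in other assays for the miR-34 and miR-449 family (camera adjusted p = 0.00939, limma design) and the miR-290 cluster (camera adjusted p = 0.00568, limma design), and for neither with an estimated correlation (adjusted p = 0.435 and 0.216). Fry, which tests a list without the other assays, gave adjusted p of 0.195 and 0.164. In KO, miR-295 was undetected at both ages and miR-293 at E16.5, so the detection limit sets the value of 2 of the 3 miR-290 assays. For the third, miR-292-3p, the KO samples at E16.5 other than replicate 3 lay at -11.3 to -11.15, at or near the limit. The test therefore decides nothing for that cluster. In no-template controls, miR-31 had a Ct of 7.58, miR-1896 of 19.5 and miR-141# of 22.0, earlier than the median Ct of the samples for these assays, 24.6, 25.8 and 22.6.

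For KO against WT at E16.5, 1 of 35 splits of the 8 samples gave as many as 146 assays, the real one. The highest other split gave 1, which argues against chance if the samples are unpaired. KO and WT pools came from littermates, and weak same-number correlations do not show that samples are unpaired. Among the 8 splits that part all numbers the highest other gave 0. If numbers pair samples, 8 splits are too few for a share under 0.05, and chance cannot be excluded. At E15.5, 1 of 35 splits of the 8 samples gave as many as 43 assays, the real one, and the highest other split gave 9. That split set replicates 1 and 2 of both genotypes against replicates 3 and 4, and did not part the numbers. As the numbers pair samples at E15.5, the real split compares with the 8 splits that part all of them, where it gave 43 and the highest other 0, and 8 splits are too few for a share under 0.05. For the difference between ages and both age comparisons the real count was 0, which 100 of 100 drawn splits and 35 of 35 splits reached. Every split reaches a count of 0, so splits test nothing for these comparisons. The highest other values were 121 for the difference, 1 for age in WT and 30 for age in KO. The draw with 121 exchanged all KO and WT labels at E16.5, and the split with 30 set KO replicates 1 and 2 of E15.5 and 2 and 3 of E16.5 against the rest, which points to a structure among the KO samples.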

How the results depend on the processing

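Scaling by set, the U6 well of the own sub-array, single sets and single wells of duplicates were chosen after seeing the data. The cause of a change was not tested unless fewer assays or samples are its construction. For KO against WT at E15.5, 43 assays became 20 with the miRNA median, 67 with U6 alone, 20 with snoRNA135, 15 with U87, 102 with Y1 and 24 with the miRNA median of the own set. The count was 26 and 3 with set 1 and set 2 alone, which hold fewer assays, 20 with the samples of that age alone, 150 with sample weights and 27 without both samples numbered 1. With the replicate block it was 19, and with the block and own-set controls also 19. The other alternatives, single samples left out aside, gave 30 to 59. At E16.5, 146 became 39 with the miRNA median, 95 with U6 alone, 56 with U87, 14 without normalization, 54 with the U6 well of the own sub-array, 50 with the miRNA median of the own set, and 79 and 29 with set 1 and set 2 alone. The other alternatives, single samples left out aside, gave 105 to 216, with rises to 178 with snoRNA135 alone, 195 with Y1 alone, 171 with the samples of that age alone, 156 with a Ct limit of 26 and 216 with sample weights. Leaving out each sample gave 14 to 112 assays at E15.5, 83 to 168 at E16.5, 0 to 0 for the difference between ages and for age in WT, and 0 to 1 for age in KO. The difference between ages gave 1 without a Ct limit and age in WT 3 with own-set controls. Age in KO gave 1 without a Ct limit, 2 with own-set controls, 3 with the U6 well of the own sub-array, 9 with the miRNA median of the own set and 14 with sample weights. The difference between ages could not be run on the samples of 1 age.

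The shift of the median at E15.5, -0.65, was 0.14 with the miRNA median and -0.82 with U6 alone (exact permutation p = 0.0286), and without each sample it was -0.92 to -0.43. At E16.5, -1.06 became -0.043 with the miRNA median, -0.46 without normalization and -0.22 with the miRNA median of the own set (exact permutation p = 0.657, 0.2 and 0.0571). With the replicate block it was -1.06 with an exact sign-flip p of 0.125, the smallest that 4 pairs allow. Without each sample it was -1.22 to -0.93, with an exact permutation p of 0.0571 without WT replicate 1 (-1.03), 2 (-0.99) or 4 (-1.05) and of 0.0286 without each of the others. The number of miRNAs detected differed by -32.4 to -11.0 at E15.5 and by -22.6 to -4.58 at E16.5 without each sample.

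Of the values of named assays under the alternatives, 190 changed sign or became 0, and of these all but those of miR-130b and miR-15b at E16.5 belong to assays that had not passed the threshold. Scaled to the miRNA median the sign changed at E15.5 for miR-18a# (0.11), miR-24 (0.0065), miR-27b# (0.71), miR-34b-5p (0.12), miR-181a (0.051), miR-181c (0.10), miR-130b (0.086), miR-152 (0.22) and miR-200c (0.071). To these come miR-196A (0.035), miR-615 (0.31), miR-10b (0.031), miR-337-3p (0.35), miR-210 (0.36), miR-9 (0.29), miR-218 (0.23), miR-126 (0.10) and miR-486 (0.27). To these come miR-451 (0.17), miR-142-3p (0.66), miR-146a (0.27), miR-150 (0.44), miR-133b (0.51), the second miR-1 assay (0.68), miR-133a (0.64) and miR-467e (0.41). At E16.5 that scaling also turned miR-181a (0.22), miR-181c (0.20), miR-130b (0.028), miR-200c (0.47), miR-429 (0.42), miR-615 (0.13) and miR-10b (0.036). To these come miR-218 (0.056), miR-126# (0.24), miR-486 (0.10), miR-451 (0.20), miR-142-3p (0.41), miR-146a (0.77) and miR-150 (0.54). Scaled to the miRNA median of the own set the sign changed at E15.5 for miR-16 (0.047), miR-24 (0.057), miR-181a (0.10), miR-181c (0.15), miR-130b (0.14), miR-152 (0.27), miR-615 (0.36) and miR-10b (0.081). To these come miR-337-3p (0.41), miR-210 (0.41), miR-128a (0.039), miR-9 (0.34), miR-218 (0.28), miR-126 (0.15), miR-486 (0.32) and miR-451 (0.22). To these come miR-142-3p (0.71), miR-146a (0.32), miR-150 (0.49), miR-133b (0.56), the second miR-1 assay (0.73), miR-133a (0.69) and miR-467e (0.46). At E16.5 that scaling also turned miR-15b (0.030), miR-181a (0.38), miR-181c (0.36), miR-130b (0.18), miR-200c (0.029), miR-429 (0.57), miR-615 (0.28), miR-10b (0.19) and miR-9 (0.16). To these come miR-218 (0.21), miR-126# (0.39), miR-486 (0.26), miR-451 (0.36), miR-155 (0.0073), miR-142-3p (0.57), miR-146a (0.93) and miR-150 (0.70). With own-set controls, with or without the replicate block or with 1 set alone the sign changed for miR-141# (-0.30), miR-142-3p (0.27), miR-150 (0.044), miR-133b (0.12), the second miR-1 assay (0.29), miR-133a (0.25) and miR-467e (0.022) at E15.5 and for miR-146a (0.13) at E16.5. With undetected values left out the sign changed for miR-27b# (0.26), miR-29b (-1.21), miR-126# (-0.30), miR-1 (-0.096) and the second miR-1 assay (0.72) at E15.5 and for miR-141# (-0.35) and miR-200b (-0.24) at E16.5. With snoRNA135 alone the sign changed for miR-27b# (0.076), miR-142-3p (0.020), the second miR-1 assay (0.040) and miR-133a (0.0064) at E15.5 and for miR-200b (-0.17) and miR-126 (-0.011) at E16.5. With Y1 alone the sign changed for miR-29b (-0.025), miR-141# (-0.100), miR-429 (-0.18) and miR-200b (-0.061) at E15.5 and for miR-200b (-0.18) and miR-126 (-0.022) at E16.5. With the U6 well of the own sub-array the sign changed for miR-141# (-0.46), miR-200b (-0.037), miR-142-3p (0.14), the second miR-1 assay (0.12) and miR-133a (0.035) at E15.5 and for miR-146a (0.19) at E16.5. Without normalization miR-141# became 0 at E15.5, and the sign changed for miR-429 (-0.082) at E15.5 and for miR-200c (0.047), miR-146a (0.35) and miR-150 (0.12) at E16.5. With U6 alone the sign changed for miR-29b (-0.0057), miR-141# (-0.080), miR-429 (-0.16) and miR-200b (-0.041) at E15.5. With sample weights the sign changed for miR-429 (-0.78) and miR-200b (-0.58) at E15.5 and for miR-200b (-0.17) and miR-126 (-0.34) at E16.5. With U87 alone the sign changed for miR-27b# (0.17), miR-142-3p (0.12), the second miR-1 assay (0.14) and miR-133a (0.10) at E15.5. With the lower-Ct well of duplicates the sign changed for miR-200b (-0.26) at E15.5 and for miR-200c (0.052) and miR-200b (-0.13) at E16.5. With a Ct limit of 26 the sign changed for the second miR-1 assay (0.39) at E15.5 and for miR-200b (-0.21) at E16.5. Without both samples numbered 1 the sign changed for miR-200c (0.20) and miR-429 (-0.18) at E15.5. With snoRNA202 alone the sign changed for miR-429 (-0.016) at E15.5. Without a Ct limit the sign changed for miR-200b (-0.67) at E15.5. Leaving out each sample took, at E15.5, miR-27b# from -0.35 to 0.26, miR-29b from -0.056 to 0.72, miR-200c from -1.27 to 0.016, miR-141# from -0.13 to 0.38 and miR-429 from -0.51 to 0.57. It also took the second miR-1 assay from -0.86 to 0.62, miR-200b from -0.34 to 0.59, miR-126# from -0.30 to 2.91, miR-142-3p from -0.49 to 0.18 and miR-133a from -0.55 to 0.20. At E16.5 it took miR-200b from -0.20 to 0.18, miR-126 from -0.27 to 0.45, miR-146a from -0.52 to 0.021 and miR-429 from -1.73 to 0.39.

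With own-set controls the mean of the Dlk1-Dio3 list minus that of the other assays was 0.019 at E15.5 and 0.029 at E16.5, and that of the Sfmbt2 list at E16.5 was -0.18. Of 21 named assays that passed at E15.5, 10 passed under each alternative that gave a value, and of 58 at E16.5, 13 did. Over all alternatives 4953 values of named assays kept direction and side of the threshold, 392 kept the direction and fell short of it, and 213 newly passed it. At E16.5 same-numbered samples did not deviate together, and the block there gave 114 assays. Apart from the counts and the named assays at E15.5, the block changed no call of a list at either age. Wells near the Ct limit bound how large a fall can be measured.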

Other observations

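The main arm and the # arm of hairpins were mostly both below WT in KO. For 32 hairpins with an assay for the main arm and for the # arm, scaled to the control wells of their own set, both arms were below WT in 24 at E15.5 and in 30 at E16.5. With 29 main arms and 26 # arms below WT at E15.5, and 30 and 32 at E16.5, independent arms would give 23.6 and 30.0, so these counts show no link between the arms. The median log2 change at E16.5 was -0.91 for the main arm and -1.08 for the # arm, and at E15.5 it was -0.61 and -0.45. Across hairpins, which are not independent replicates and whose arms were read in the same samples, the arms had a Pearson r of 0.556 and a Spearman rho of 0.622 at E15.5, and 0.621 and 0.625 at E16.5. These hairpins were gathered after the data were seen.

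In WT replicate 2 at E16.5 the muscle miRNAs miR-133a and miR-206 had levels of 1.86 and 1.503, against -4.24 to -2.53 and -4.29 to -3.04 in the other WT samples of that age. These assays were picked after seeing the data.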
